A study of Mus musculus with 2 samples.

How the data were processed

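Cells of the thoracic esophagus from 2 mouse genotypes were profiled by droplet 3′ single-cell RNA sequencing, with 1 library per genotype (WT and K5:Smo). The files used here were, for each library, the list of barcodes called as cells and the list of features. Both hold text identifiers and no measured values. Per the submitters' processing notes, bcl2fastq, STAR and Cell Ranger 9.0.0 were used with build mm10; the notes give no role or order for them. Per the labels, the sorted cells were processed with a Chromium 3′ kit, named as v3 for the capture step and v4 for library construction, and sequenced on a NovaSeq. The deposited lists carry the name of a filtered matrix, so the authors' cell calling had been applied before deposit; its settings are not given in the sources used here. The count matrices were not analysed here. Steps planned for them (cell filters, doublet calling, clustering, shares of cell classes and differences per gene) were therefore not carried out, and the depth of each library is unknown.

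Samples were grouped by the genotype in the labels. Each barcode consisted of 16 bases and 1 common suffix, and no barcode was repeated within a library. The suffix was removed and the sequences were compared between libraries by exact match. The chance number of shared barcodes was the product of both barcode numbers divided by the size of the barcode list, taken as about 6800000 (3′ v3) with about 3700000 (3′ v4) as the alternative. These sizes are rounded settings from general knowledge of the kits, and do not come from the files. Barcode pairs 1 and 2 bases apart were enumerated within and between libraries. Numbers of barcodes and pairs carry exact 95% Poisson intervals, which cover counting error only. Those for pairs treat the pairs as independent, although pairs have barcodes in common. The list size was also estimated from the barcodes themselves: each was split into its first 7 bases, the middle bases 8 and 9, and its last 7 bases. The numbers of different first and last parts per middle were corrected for unseen ones with the Chao1 estimator, and their products were summed over the middles. The overlap and list-size computations were tested on simulated barcodes in libraries of the real sizes. These were drawn from a list far shorter than those considered here. The pair computation was tested on a smaller set of random sequences without this division into parts. In the simulated libraries the list size came out at 100% of the true size. From so short a list almost every first and last part is drawn. That result therefore does not test the correction for unseen parts. The way the 40 shared barcodes were planted made recovery of 40 of 40 certain. Among the random sequences, 25 of 25 planted pairs were recovered. The number of barcodes shared by chance was 93.3% of the number expected in the simulated libraries. In 20 further draws it averaged 102%, with a range of 96.8% to 112%. A shorter list gives more shared barcodes, so this spread is narrower than that of the real overlap.

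Feature IDs were matched to GENCODE vM21 (GRCm38) without version numbers. Of the 32285 mouse IDs, 32235 matched and 50 did not, and 733 of the matched IDs had another symbol there, so vM21 was not exactly the annotation behind the feature list. All 179 fixed genes matched by ID and symbol. Biotypes, coordinates and exons were taken from vM21. A gene was said to share exonic bases where any base of its merged exons lay in an exon of another listed feature on the same strand.

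The gene lists (8 lists), the marker lists (17 lists) and the rule for named genes were fixed before the data were examined. Without count matrices, the rule named the list members absent from the features, the symbols listed more than once and the features that are not Ensembl mouse genes. No list member was absent. The 5 genes given with coordinates were picked afterwards from the fixed lists without regard to any measured value. No test between genotypes was made, since each has 1 library. Python 3.11.15 and SciPy 1.17.1 were used.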

Results

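The data concern single cells from the thoracic part of the mouse esophagus, profiled with a droplet 3′ RNA assay in which each cell's transcripts carry a common barcode. One library came from wild-type (WT) mice. The other came from K5:Smo mice, sampled 5 days after tamoxifen. The labels of the WT sample do not say whether those mice received tamoxifen. In K5:Smo mice, tamoxifen switches on a Cre recombinase made in keratin 5-expressing cells, which include the basal progenitors of the stratified epithelium. The recombinase then turns on SmoM2, an active form of Smoothened, the membrane protein that transmits the Hedgehog signal, together with a yellow fluorescent protein. Per the labels, living cells were sorted by EpCam, an epithelial surface protein. The design sets the transcriptomes of esophageal cells of the WT and K5:Smo genotypes side by side, and the libraries may differ in tamoxifen treatment as well as in genotype. The lists of cells and of counted genes were analysed here. The matrices of transcript counts were not analysed here, so no gene's level, no cell type's share and no sequencing depth can be given for either genotype, and none of the values that follow is a measurement of expression.

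The first comparison concerned how many cells each library contributed. The WT library held 13607 barcodes called as cells, with an exact 95% Poisson interval of 13379 to 13838. The K5:Smo library held 13618, with an interval of 13390 to 13849. The K5:Smo library thus had 11 barcodes more, a ratio of 1.00, and the difference lay within the counting error of either number. These intervals cover counting error only. With 1 library per genotype there was no replicate check, and no test between genotypes was made. The number of barcodes follows the number of cells loaded and the cell calling, and is not a measure of the cells in the tissue.

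The genes that could be counted were identical in both libraries. Each list held 32290 features in the same order, and 0 lines differed between them. Of these, 32285 were Ensembl mouse genes and 5 were added sequences, named CRE, EGFP, mCherry, TdTomato and YFP. YFP is the feature that bears on the SmoM2/EYFP allele, and CRE the one that bears on the Krt5-CreERT2 driver. No feature was named for SmoM2 itself, and Smo was listed once, as the mouse gene. Whether reads from the SmoM2 allele would be counted under Smo was not tested. A count for Smo could therefore not be taken as that of the endogenous gene alone. EGFP and YFP are close relatives in sequence, so any count under either name is uncertain where reads fit both. Neither was measured here.

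Every gene of the Hedgehog list fixed before the data were examined was present among the features, 16 of 16. Gli1, a transcription factor and direct target of the pathway (ENSMUSG00000025407), lies on chromosome 10 from 127329882 to 127341974 on the minus strand. Ptch1, the Hedgehog receptor that restrains Smoothened (ENSMUSG00000021466), lies on chromosome 13 from 63508328 to 63573598 on the minus strand. Hhip, which binds and sequesters the ligands (ENSMUSG00000064325), lies on chromosome 8 from 79965851 to 80058006 on the minus strand. Smo (ENSMUSG00000001761) lies on chromosome 6 from 29735503 to 29761365 on the plus strand. Krt5, whose promoter drives the recombinase (ENSMUSG00000061527), lies on chromosome 15 from 101707070 to 101712898 on the minus strand. These coordinates are 1-based, from GENCODE vM21 on GRCm38, the assembly also called mm10. All 5 genes are annotated as protein-coding, and each span runs from the gene's first to its last annotated base.

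The other fixed lists were also complete. The columnar or embryonic esophagus list had 16 of 16 members, among them Sox9, Krt7, Krt8 and Krt18. The basal progenitor list had 10 of 10, with Krt5, Krt14, Krt15 and Trp63, and the suprabasal list had 12 of 12, with Krt4, Krt13 and Sbsn. The cell cycle list had 15 of 15, the Wnt target list 10 of 10, the interferon list 8 of 8 and the dissociation stress list 10 of 10. All 17 cell type marker lists were complete as well, covering basal and suprabasal keratinocytes, fibroblasts, smooth muscle or pericytes, striated muscle, blood and lymphatic endothelium, macrophages or monocytes, dendritic or Langerhans cells, T or NK cells, B cells, neutrophils, mast cells, Schwann or neural cells, melanocytes, mesothelium and erythrocytes. In all, 179 distinct genes were sought and 0 were absent. The feature list held 98.5% of the protein-coding genes of GENCODE vM21, so complete lists say little about these libraries. Presence in the list says that reads could be assigned to a gene, not that any were.

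None of the 179 genes shared an exonic base on its own strand with another listed feature in GENCODE vM21. Over the whole list, 803 of 32235 matched features did, or 2.49%, which corresponds to 4.46 genes in a list of that size. That share covers all gene classes, including lincRNA and antisense genes, whereas the fixed genes are nearly all protein-coding. The 2 sets are therefore not alike, and a share for protein-coding genes alone was not computed. Sharing of exonic bases matters because reads that fit more than 1 gene cannot be assigned by position. It does not cover near-identical copies elsewhere in the genome, such as Hspa1a and Hspa1b, heat shock genes in the stress list. Any counts for those 2 genes are uncertain where reads fit both. Overlap with the introns of other features was not examined either.

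Of the features matched to GENCODE vM21, 21702 were protein-coding, 98.5% of the protein-coding genes of that annotation. The list also held 5605 lincRNA genes and 2955 antisense genes, but 0 of 2207 microRNA genes and 1 of 9941 processed pseudogenes. On the mitochondrial chromosome 13 features were listed, and neither of the 2 mitochondrial ribosomal RNA genes was among them. A symbol was not always unique, since 38 symbols were given to 78 gene IDs. They included the chemokines Ccl19, Ccl21a, Ccl21b, Ccl21c and Ccl27a, the glycolytic enzyme Aldoa, the stress-response factor Ddit3 and the mitochondrial transhydrogenase Nnt. The others with established names were Arhgef4, Btbd35f1, Dpep2, Fam205a4, Fam220a, Fam90a1b, Ighv1-13, Ighv5-8, Il11ra2, Jakmip1, Olfr290, Pakap, Pcdha11, Ptp4a1, Sept2, Snhg4, St6galnac2 and Zc3h11a. The remaining symbols were 4930594M22Rik, C730027H18Rik, Gm16364, Gm16499, Gm16701, Gm28710, Gm3286, Gm35438, Gm35558, Gm38619, Gm41392 and Gm5089. None of the 179 fixed genes was among the repeated symbols.

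The last comparison asked whether the libraries shared cell barcodes beyond chance. They had 51 barcode sequences in common, 0.375% of the barcodes of either library, with an exact 95% Poisson interval of 38.0 to 67.1. Independent draws of these sizes from a list of about 6800000 barcodes, the approximate size for the 3′ v3 kit, would share 27.3. Draws from a list of about 3700000, the approximate size for the 3′ v4 kit, would share 50.1. The observed number lay above the first value by more than its interval and within its interval of the second. The labels name both kit versions. No 2 barcodes of a library were 1 base apart, and none of the WT barcodes was 1 base from a K5:Smo barcode. Whether the kit's list holds any such pairs was not tested. Their absence therefore says nothing about sequence errors or carried-over barcodes. At 2 bases apart there were 117 pairs per 10000000 possible pairs within the WT library (95% Poisson interval 110.1 to 124.2). There were 120.3 within the K5:Smo library (113 to 128) and 118 between them (113 to 123), so the intervals overlapped. Each barcode enters many pairs, so pairs are not independent, and these intervals may misstate the counting error.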

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

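The chance number of shared barcodes depended on the assumed list, rising from 27.3 to 50.1 with the 3′ v4 list and to 50.3 with the list size estimated from the barcodes, an alternative chosen after seeing the data. Allowing 2 differing bases in place of 1 raised the number of near barcode pairs from 0 to 1083 in WT, 1115 in K5:Smo and 2181 between the libraries. Leaving out shared barcodes gave 13556 in WT and 13567 in K5:Smo, within the counting error of the full numbers. With only 51 shared barcodes, leaving them out could not take either number outside its interval. There were 32250 unique symbols against 32290 features. The remaining alternatives could not move their results and say nothing about stability. With 0 pairs of barcodes 1 base apart, allowing 1 differing base or counting such barcodes once had nothing to act on. With 179 of 179 list members present, ignoring case could add none. The basic transcripts, chosen after seeing the data, are part of the full set, in which 0 members shared exonic bases. Alternatives set out before the data were examined for shares of cells (filters, doublets, clustering resolution) and for differences per gene (normalization, thinning, minimum counts) were not run, because the count matrices were not analysed here. The depth of each library is unknown, so how far it set the number of barcodes called as cells was not tested.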

Other observations

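The comparison of the shared barcodes with the kits' list sizes was set before the data were examined; the tests that use the structure of the barcodes were chosen after the result was seen. The 51 barcodes common to both libraries exceeded the 27.3 that a list of 6800000 barcodes gives. The barcodes had a regular structure: in all 27225 of them, bases 8 and 9 took only 4 values (AG, CA, GT and TC), each in 24.7% to 25.4% of a library's barcodes. Each of the 3835 different first parts of 7 bases, and each of the 3832 different last parts, occurred with 1 middle only. If every first part can be joined to every last part with the same middle, the WT library alone gives a list of 3673078 barcodes and the K5:Smo library alone one of 3693924. Both estimates are below 6800000, which argues against barcodes carried between the libraries on top of the longer list. The WT estimate predicts 50.4 shared barcodes, within the 38.0 to 67.1 interval of the observed number. A candidate explanation is that both libraries were made with the shorter list, that of the 3′ v4 kit, which is one of the versions the labels name. The observed number exceeded the chance number from both libraries' parts by only 0.706. That chance number lay inside the interval, so the excess is no sign of carried-over barcodes. A few carried-over barcodes stay open because the interval is wide, with an upper end 16.8 above the chance number. No biological explanation was tested.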
